A study of Mus musculus with 11 samples.

How the data were processed

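ATAC-seq libraries came from purified mouse bone marrow HSCs of the genotype Gfplc3/Gfplc3, isolated at steady state. The labels give 5 young libraries and 3 pairs of old libraries, each pair sorted by GFP into an AThi and an ATlo library. Per the labels' protocols, transposition took 30 min at 37 °C, libraries were prepared on a single day, fragments above 1000 bp were removed, and sequencing was paired end with 150 bp reads. Isolation and transposition took place over 2 days, and the day of each sample, the sex and the age in numbers were not given in the sources used here. Age group therefore could not be separated from these factors in the comparisons with young HSCs, in which fractionation also differs. Between AThi and ATlo HSCs, sex and age are shared within each pair. The labels call the old pairs biological replicates but do not say from how many animals each library came, so p-values measure the spread between these libraries.

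The submitters' processing notes name Trim Galore, cutadapt, BWA, MACS2, featureCounts, DESeq2 and ChIPseeker without versions or settings. Whether reads were shifted for the transposase, how duplicates and mitochondrial reads were treated and how peaks of different libraries were merged was not given in the sources used here. These steps set where peaks lie and which are kept. The deposited files were 3 tables of the authors' own comparisons over the same 94410 peaks, with the peaks' positions and nearest genes. The authors' mean level per peak is a normalised count averaged over libraries, used as a signal value that is never negative. The authors' deposited log2 fold changes came with SEs on the same scale. The Wald statistic per peak, the fold change over its SE, is the authors' score. The authors' deposited p-values and Benjamini-Hochberg adjusted p-values were used as they stand. An adjusted p was missing for 1831 peaks in each comparison with young HSCs, all with a mean normalised count of at most 5.96, and these peaks were not called. All 3 tables came from 1 fit: the AThi against young change minus the ATlo against young change equalled the AThi against ATlo change to within 1.02e-14. The fit thus shares an estimate of the spread over all groups.

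The design written before the data were examined assumed counts per library, with the authors' comparisons as the fallback. The files held 0 columns of values per sample, so no model was refitted and the authors' calls at an adjusted p under 0.05 were used. Fits that leave out a library, block on the pair, use other size factors or count filters, or split the samples otherwise were not run for the same reason. Depth per library could not be checked. Precision was taken from the SEs, with 95% intervals as 1.96 SE on each side of the log2 change.

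The submitters' processing notes name both GRCm38 and mm39. Peak coordinates were taken as mm39, 1-based, because 15.3% of peaks lay over the tables' own transcription start sites and 0.481% over gene starts of the RefSeq GRCm38.p6 table, and only 273 of 20791 genes ended at the same base. The RefSeq table was used for names alone and matched 20791 of 20810 gene identifiers, leaving 19 identifiers at 42 peaks without a symbol. Peaks carry the gene with the nearest start site in the authors' annotation. Exon and intron numbers belong to the overlapping transcript, whose gene can differ from the assigned one, and both are then given. A peak near a gene is not a measurement of that gene's expression.

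Named genes followed a rule fixed before the data were examined. For each comparison with young HSCs it took the 10 genes with the smallest p among higher peaks and the 10 among lower peaks, with an adjusted p under 0.05 and at least a 2-fold change, passing over predicted genes. Where fewer than 5 peaks passed, the 5 with the smallest p in each direction were taken and named as not passing. The rule added up to 4 members of each list with the smallest p, and Map1lc3b, Foxo3, Hlf, Selp and Gapdh. Further called members of lists were named as examples after their values were seen. An item that the rule selected is not reported here.

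Lists of autophagy, lysosomal, FoxO, glycolysis, mitochondrial, NF-κB, interferon, JAK-STAT, AP-1, HSC identity, HSC ageing, lymphoid, myeloid, megakaryocyte and erythroid, stromal and endothelial, cell cycle, chromatin, and TGF-β, BMP and Wnt genes, 18 in all with 524 genes, were fixed before the data were examined. A peak was found for 506 of these genes. The mean over genes of the mean Wald statistic of a gene's peaks was compared with 10000 random lists of genes matched on the number of peaks, two-sided, with Benjamini-Hochberg adjustment over the 18 lists of a comparison. The deviation is the difference from the mean of the random lists, and the smallest p that they can give is 0.0001. This test treats genes as independent, so its p-values may be too small where members vary together between libraries. No correlation between genes could be estimated. The test was tested on simulated data over 20810 genes, with independent noise of SD 1 per peak. Lists shifted by 0.5 or by 1 in the mean statistic were called in 100% of 20 simulated lists each. Of 280 lists without a shift, 1.07% were called. The Wald statistics against young HSCs had SDs of 1.84 (AThi) and 1.75 (ATlo), so a shift of 0.5 can be missed there. A gene was counted as higher or lower if any of its peaks was called, and in both directions if peaks of both kinds were.

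For the overlap of the comparisons with young HSCs, the covariance from the shared young libraries was derived from the SEs of all 3 comparisons, and 100 draws of unchanged groups were made with it. In a test on simulated data, a shared variance of 0.1 was recovered as 0.0997. For peaks called in 1 fraction alone, the change of an unchanged other fraction was drawn given the selected change and kept where it stayed below the smallest called statistic, which was added after seeing the data. Shares of genomic classes were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Alternatives were other adjusted p limits (0.01 and 0.1), a 2-fold limit, promoter peaks alone, peaks above the median level, adjustment over all peaks, a gene's peak with the smallest p, and settings added after seeing the data. The trend with peak level was removed by subtracting, from each Wald statistic, the median of peaks in the same of 20 level bins and with the same promoter status, where promoter peaks lay within 1000 bp of a start site. The 18 planned motifs were not analysed here, since no mm39 genome was used here. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.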

Results

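Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in haematopoietic stem cells (HSCs) purified from mouse bone marrow. The mice carried a GFP-LC3 reporter allele. LC3 marks autophagosomes, and the GFP signal is lost as autophagy degrades it. HSCs of old mice were sorted into a fraction with low GFP, AThi, labelled as engaging autophagy, and a fraction with high GFP, ATlo, labelled as not engaging it. There were 5 libraries of young HSCs, which were not fractionated, 3 of old AThi HSCs and 3 of old ATlo HSCs. The authors' deposited tables gave log2 fold changes, standard errors (SE) and p-values for 94410 peaks of 201 to 4100 bp (median 547 bp) in 3 comparisons. The mean normalised count per peak had a median of 27.5 in the authors' deposited tables and summed to 5967520 over all peaks. Depth per library was not given in the sources used here. The comparisons ask how each old fraction differed from young HSCs, and how the old fractions differed from each other. Age and fractionation differ together in both comparisons with young, since young HSCs were not sorted by GFP.

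Old AThi HSCs had higher accessibility than young HSCs at genes known as markers of HSC ageing. Cell cycle genes, myeloid genes and mitochondrial regulators lay lower as lists, although some of their members, such as Cdkn2a, rose. These list calls ended under some of the alternative settings given below. In the authors' deposited table, the promoter of Cavin2, a component of caveolae, was 2.13-fold more accessible (log2 1.09, SE 0.17, adjusted p = 2.22e-08). The 3′ UTR peak of Enpp5 on chromosome 17 (44394026 to 44394573) was 8.34-fold higher (log2 3.06, SE 0.37, adjusted p = 8.69e-14) in the authors' deposited table. Per the authors' deposited table, the promoter of Cdkn2a, which encodes the cell cycle inhibitor p16 and the tumour suppressor ARF, was 3.52-fold higher (log2 1.81, SE 0.28, adjusted p = 1.49e-08). A distal intergenic peak upstream of Csf1r, the receptor for macrophage colony-stimulating factor, fell by 1.75 on the log2 scale (SE 0.32, adjusted p = 3.57e-06) in the authors' deposited table.

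Of all peaks, 7004 were called higher and 2539 lower in old AThi HSCs than in young HSCs at an adjusted p under 0.05, so that 73.4% of calls were higher. Called peaks lay at 4953 genes with a higher peak and 2198 genes with a lower one. The median log2 change was 1.21 among higher calls and -0.85 among lower calls, and 4616 higher and 1025 lower calls changed at least 2-fold. An added scaling, chosen after seeing the data, moved the median log2 change of the 1811 strongest promoters (mean normalised count of at least 356) from -0.22 to 0, and every other peak with it. With it 12631 peaks were called higher and 802 lower, or 94.0% higher, so the split of calls by direction rests on the scaling.

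The smallest adjusted p among higher calls belonged to a peak on chromosome 5 (127614254 to 127615075) in intron 5 of Tmem132c, assigned to Slc15a4. It was 17.7-fold higher in old AThi than in young HSCs (log2 4.15, SE 0.32, adjusted p = 1.67e-33) in the authors' deposited table. A peak in exon 41 of Ubr4, a ubiquitin ligase, on chromosome 4 (139151746 to 139152363) was 5.62-fold higher (log2 2.49, SE 0.19) in the authors' deposited table. In the authors' deposited table, promoters among these calls had log2 changes of 2.71 (SE 0.22) at Dpp6, a potassium channel subunit, 2.08 (SE 0.17) at Nkain2, 2.25 (SE 0.20) at Pdzrn4 and 2.16 (SE 0.20) at Astn2. The authors' deposited table gave log2 changes of 3.00 (SE 0.25) for a peak in exon 40 of Abca1 assigned to Nipsnap3b, 2.61 (SE 0.22) for a distal peak of Wars2, 3.46 (SE 0.31) for intron 15 of Mfsd1 and 3.21 (SE 0.29) for exon 5 of Tyms, the thymidylate synthase. Among lower calls, a peak in exon 4 of Iscu, an iron-sulphur cluster scaffold, on chromosome 5 (113914892 to 113915334) fell by 2.95 (log2, SE 0.38, adjusted p = 3.85e-12) in the authors' deposited table. Lower log2 changes in the authors' deposited table included -3.05 (SE 0.42) in exon 6 of Emc3, -2.56 (SE 0.38) in intron 12 of Csmd1 (assigned to Mir3106), -1.96 (SE 0.29) at a distal peak of Zfp658 and -1.54 (SE 0.23) in exon 10 of Plekha2 (assigned to Htra4). Further down, the authors' deposited table listed -1.21 (SE 0.19) at the Arhgap30 promoter, -1.58 (SE 0.25) in exon 18 of Adgra2 (assigned to Brf2), -1.39 (SE 0.22) at a distal peak of Bclaf3 on the X chromosome, -1.95 (SE 0.32) in a 3′ UTR assigned to Snora5c and -1.64 (SE 0.27) at the Zfp316 promoter.

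Of the 32 HSC ageing markers with a peak, 24 had a peak that rose in old AThi HSCs, 1 had a peak that fell and 7 had neither, where random genes with as many peaks gave 11.5 with a higher peak. The list lay above matched random lists (mean Wald statistic higher by 1.56, adjusted p = 0.0018). It held 50 higher peaks and 1 lower peak adjusted over all peaks, and 61 and 3 adjusted over the list alone. Log2 changes in the authors' deposited table were 1.37 (SE 0.23) at the promoter of Clca3a1, 0.88 (SE 0.16) at a distal peak of Ehd3, 1.12 (SE 0.21) at the promoter of Clu and 1.37 (SE 0.35) in intron 1 of Selp, which encodes P-selectin. Selp's promoter changed by 0.96 (SE 0.27, adjusted p = 0.0067) in the authors' deposited table. The member that fell was Ptger4, a prostaglandin E2 receptor, with a promoter change of -1.05 (SE 0.28, adjusted p = 0.00441) in the authors' deposited table.

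Cell cycle and DNA damage genes lay lower as a list in old AThi HSCs (deviation -0.72, adjusted p = 0.018): of 32 genes, 4 had a higher peak, 8 a lower peak and 22 neither, with 2 counted in both directions. The higher members were Cdkn2a, Cdkn2b, which encodes the inhibitor p15, and the cyclins Ccne1 and Ccne2, with log2 changes in the authors' deposited table of 1.72 (SE 0.39) for the Cdkn2b peak, 2.03 (SE 0.29) for Ccne1 and 1.13 (SE 0.23) for the Ccne2 promoter. Promoters of Ccnd2, a cyclin that drives entry into the cycle, and of the proliferation marker Mki67 fell by 0.52 (SE 0.14) and by 0.49 (SE 0.17) on the log2 scale in the authors' deposited table. Adjusted over the list alone, 4 peaks were higher and 6 lower, against 4 and 9 adjusted over all peaks. Mitochondrial regulators lay lower (deviation -0.78, adjusted p = 0.0355), although of 22 genes 2 had a higher peak, 1 a lower peak and 19 neither. In the authors' deposited table, the promoter of Polg, the mitochondrial DNA polymerase, changed by -0.44 (SE 0.14, adjusted p = 0.0189), while distal peaks of Vdac1 and of Ppargc1a, the coactivator PGC-1α, rose by 1.97 (SE 0.30) and 2.29 (SE 0.47). Myeloid genes lay lower (deviation -0.63, adjusted p = 0.0355), with 4 of 29 genes having a higher peak, 5 a lower peak and 22 neither. For cell cycle genes, random genes with as many peaks gave 8.39 with a higher and 3.61 with a lower peak. They gave 5.27 and 2.23 for mitochondrial regulators and 7.31 and 3.24 for myeloid genes. Besides Csf1r, the authors' deposited table gave -1.66 (SE 0.50) at the promoter of Fcgr3, an Fc receptor, 0.95 (SE 0.23) at the promoter of Cebpb and 1.34 (SE 0.32) in intron 1 of Cx3cr1. Removing the trend of the Wald statistic with peak level, chosen after seeing the data, ended the calls for cell cycle genes (deviation -0.48, SD of random lists 0.220, adjusted p = 0.177) and mitochondrial regulators (-0.49, SD 0.266, adjusted p = 0.194). Myeloid genes still passed under that setting (-0.71, SD 0.225, adjusted p = 0.0234). With promoter peaks alone, myeloid genes kept a deviation of -0.68 but did not pass (adjusted p = 0.234), as the SD of random lists rose from 0.232 to 0.368. None of these 3 lists passed with each gene's smallest-p peak (adjusted p = 0.184 for each). Their deviations were then -1.08 for cell cycle, -1.31 for mitochondrial and -1.04 for myeloid genes. The SDs of random lists rose from 0.229, 0.276 and 0.232 to 0.506, 0.612 and 0.537. A gene's most extreme statistic varies more than its mean, so deviations of these settings do not compare in size. Relative to the SD, all 3 deviations were smaller than with the mean.

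The other 14 lists did not pass against matched random lists in old AThi HSCs. Random genes with as many peaks gave 9.18 with a higher and 4.16 with a lower peak for autophagy genes. They gave 12.3 and 5.56 for AP-1, and 14.9 and 8.06 for HSC identity genes. For TGF-β, BMP and Wnt genes they gave 13.0 and 5.86, and for stromal and endothelial markers 6.64 and 3.13. Autophagy genes (adjusted p = 0.586) had 6 of 36 members with a higher peak and 2 with a lower one, among them Wdfy3 (intron 8, log2 1.35, SE 0.23), the receptor Optn (intron 4, 0.89, SE 0.19) and Atg14 (3′ UTR, -1.87, SE 0.58) in the authors' deposited table. The promoter of Map1lc3b, an LC3 gene, did not pass (log2 -0.43, SE 0.17, adjusted p = 0.0808) in the authors' deposited table. Among lysosomal genes (adjusted p = 0.349), intron 1 of the protease gene Ctsb rose by 1.80 (SE 0.18) and an intron 1 peak of Tfeb, a regulator of lysosomal genes, rose by 1.03 (SE 0.24) in the authors' deposited table. FoxO factors and targets (adjusted p = 0.0543) included Foxo3, whose intron 2 peak rose by 0.89 (SE 0.21) while its promoter fell by 0.40 (SE 0.14) in the authors' deposited table. Glycolysis genes (adjusted p = 0.0543) included the Eno1 promoter at 1.60 (SE 0.27) and intron 2 of hexokinase 2, Hk2, at 1.03 (SE 0.17) in the authors' deposited table. AP-1 and immediate early genes (adjusted p = 0.956) had 14 of 29 members with a higher peak and 8 with a lower one, and the promoters of Fos and Jun rose by 1.12 (SE 0.18) and 1.06 (SE 0.18) in the authors' deposited table. HSC identity genes (adjusted p = 0.393) had 18 of 32 members with a higher peak and 7 with a lower one. Intron 1 of Mecom and the Gata2 promoter rose by 1.87 (SE 0.32) and 0.90 (SE 0.17) in the authors' deposited table, and a distal peak of Hlf rose by 1.43 (SE 0.50, adjusted p = 0.0456), while the Hlf promoter did not pass (-0.28, SE 0.19). TGF-β, BMP and Wnt genes had an adjusted p of 0.774, with 14 of 27 members having a higher peak, including intron 1 of the receptor gene Tgfbr1 (log2 2.40, SE 0.38) in the authors' deposited table. Stromal and endothelial markers, which stand for other cell types of the marrow, gave an adjusted p of 0.64. Of these 22 genes 6 had a higher peak and 3 a lower one, and the Cxcl12 promoter and exon 3 of Plvap rose by 1.27 (SE 0.19) and 1.83 (SE 0.25) in the authors' deposited table. Adjusted p-values were 0.64 for interferon response and for JAK-STAT genes, 0.272 for NF-κB genes, 0.374 for chromatin regulators, 0.586 for lymphoid genes and 0.684 for megakaryocyte and erythroid genes. The Gapdh promoter did not pass in the authors' deposited table (log2 -0.15, SE 0.14, adjusted p = 0.589).

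Old ATlo HSCs had higher accessibility than young HSCs at HSC ageing markers and lower accessibility at mitochondrial regulators as a list. FoxO genes and chromatin regulators also lay lower as lists, and called peaks of all 3 lists went both ways. Cell cycle genes (deviation -0.79), myeloid genes (-0.68), NF-κB genes and glycolysis genes lay lower too, with alternative settings given below. In old AThi HSCs the cell cycle, myeloid and mitochondrial lists had also passed as lower (-0.72, -0.63 and -0.78). With each gene's smallest-p peak the FoxO and chromatin lists did not pass. Their deviations were then -1.57 and -1.10, with SDs of random lists of 0.649 and 0.543. With the mean over peaks they were -0.68 and -0.67, with SDs of 0.199 and 0.211. Relative to the SD, both deviations were thus smaller with the smallest-p peaks. The Clca3a1 promoter on chromosome 3 (144466259 to 144467105) was 2.88-fold higher (log2 1.53, SE 0.22, adjusted p = 1.53e-09) and the Clu promoter 2.36-fold higher (log2 1.24, SE 0.21) in the authors' deposited table. Per the authors' deposited table, the promoter of Polg on chromosome 7 (79115241 to 79116769) fell by 0.69 on the log2 scale (SE 0.14, adjusted p = 3.42e-05). The distal Csf1r peak on chromosome 18 (61223592 to 61224520) fell by 2.49 (log2, SE 0.35, adjusted p = 2.52e-10) in the authors' deposited table.

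In old ATlo HSCs 6370 peaks were called higher and 2351 lower than in young HSCs, or 73.0% higher, with a median log2 change of 1.20 and -0.61. At least 2-fold changes were found at 4154 higher and 530 lower peaks, and called peaks lay at 4540 and 2093 genes. With the median of the strongest promoters moved from -0.31 to 0, a scaling chosen after seeing the data, 16007 peaks were called higher and 296 lower, or 98.2% higher. Among promoter peaks alone, 48.8% of calls were higher.

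The peak in intron 5 of Tmem132c assigned to Slc15a4 again had the smallest adjusted p among higher calls, at a log2 change of 4.04 (SE 0.32, adjusted p = 5.01e-32) in the authors' deposited table. The authors' deposited table gave log2 changes of 2.63 (SE 0.22) at the promoter of the ephrin receptor gene Epha6, 2.52 (SE 0.22) at the Dpp6 promoter, 2.26 (SE 0.19) in exon 41 of Ubr4 and 2.55 (SE 0.22) at the distal Wars2 peak. The 3′ UTR peak of Kcnj11, a potassium channel gene, rose by 2.95 (SE 0.28), intron 3 of Rbfox3 (assigned to Engase) by 3.32 (SE 0.32), intron 16 of Man2a1 (assigned to Dreh) by 2.08 (SE 0.20), a distal peak of Ppa2 by 2.94 (SE 0.28) and intron 15 of Mfsd1 by 3.41 (SE 0.30) in the authors' deposited table. Lower peaks in the authors' deposited table included exon 4 of Iscu (log2 -3.39, SE 0.39), exon 6 of Emc3 (-2.46, SE 0.34), intron 12 of Csmd1 (-3.06, SE 0.39) and the Rnf220 promoter (-1.03, SE 0.17). Also lower in the authors' deposited table were exon 10 of Plekha2 (log2 -1.51, SE 0.22), intron 1 of Rassf4 (-1.33, SE 0.22), a distal peak of Atp10a (-1.55, SE 0.26), the 3′ UTR of Fam131a (-1.32, SE 0.22) and the distal Bclaf3 peak (-1.27, SE 0.21). The other peaks named for AThi HSCs had ATlo changes, in the authors' deposited table, of 1.78 (SE 0.17) at Nkain2, 2.51 (SE 0.25) in Abca1, 2.55 (SE 0.29) at Tyms, 2.01 (SE 0.20) at Pdzrn4 and 2.00 (SE 0.20) at Astn2. For the lower ones the authors' deposited table gave -1.48 (SE 0.26) at Zfp658, -1.05 (SE 0.19) at Arhgap30, -0.97 (SE 0.22) in Adgra2 and -1.34 (SE 0.25) at Zfp316, while Snora5c did not pass (-0.65, SE 0.26, adjusted p = 0.0891). AThi changes at the peaks named for ATlo HSCs were, in the authors' deposited table, 2.43 (SE 0.23) at Epha6, 2.70 (SE 0.29) at Kcnj11, 3.15 (SE 0.32) in Rbfox3, 2.15 (SE 0.20) in Man2a1 and 2.67 (SE 0.29) at Ppa2. They were -0.55 (SE 0.16) at Rnf220, -1.09 (SE 0.22) at Rassf4, -1.67 (SE 0.28) at Atp10a and -1.28 (SE 0.23) at Fam131a in the authors' deposited table.

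HSC ageing markers lay higher in old ATlo HSCs (deviation 1.54, adjusted p = 0.0009): 25 of 32 genes had a higher peak against 10.6 for random genes, 3 had a lower peak and 5 had neither. Adjusted over all peaks 50 of their peaks were higher and 3 lower, and adjusted over the list alone 65 and 7. In the authors' deposited table, the 3′ UTR peak of Enpp5 rose by 3.03 (SE 0.37), a distal peak of the nuclear receptor gene Rorb by 3.82 (SE 0.65), the Cavin2 promoter by 0.94 (SE 0.17), the distal Ehd3 peak by 0.92 (SE 0.16) and intron 1 of Selp by 1.18 (SE 0.35). Selp's promoter did not pass (log2 0.70, SE 0.27, adjusted p = 0.0791) in the authors' deposited table, and the Rorb peak changed by 2.97 (SE 0.69) in old AThi HSCs.

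Mitochondrial regulators lay lower in old ATlo HSCs (deviation -1.19, adjusted p = 0.0009), with 3 of 22 genes having a higher peak, 7 a lower peak and 13 neither. Their peaks counted 3 higher and 7 lower adjusted over all peaks, and 7 and 12 adjusted over the list alone. Beside Polg, the promoter of Mff, a mitochondrial fission factor, fell by 0.52 (SE 0.16) and that of the nuclear receptor gene Esrra by 0.55 (SE 0.17) in the authors' deposited table, whereas distal Ppargc1a and Vdac1 peaks rose by 2.37 (SE 0.46) and 1.44 (SE 0.30). FoxO factors and targets lay lower (deviation -0.68, adjusted p = 0.00675), with 8 of 24 genes having a higher peak, 10 a lower peak and 11 neither. In the authors' deposited table, the Foxo3 promoter on chromosome 10 (42153253 to 42154429) fell by 0.51 (SE 0.14, adjusted p = 0.00471) and exon 9 of Sesn2 by 1.73 (SE 0.46), and the intron 2 peak of Foxo3 did not pass (0.53, SE 0.21, adjusted p = 0.0911). Distal S1pr1 and intronic Acoxl (assigned to Bcl2l11) peaks rose by 1.66 (SE 0.32) and 1.99 (SE 0.32) in the authors' deposited table. Chromatin and DNA methylation regulators lay lower (deviation -0.67, adjusted p = 0.00972), with 6 of 28 genes having a higher peak, 8 a lower peak and 16 neither. Promoters of Eed, a subunit of Polycomb complex PRC2, of the acetyltransferase gene Kat6a and of Bmi1 fell by 0.60 (SE 0.16), by 0.94 (SE 0.22) and by 0.60 (SE 0.18) in the authors' deposited table, while intron 2 of Hdac9 rose by 1.22 (SE 0.20). Adjusted over the list alone, 9 FoxO peaks were higher and 12 lower, and 11 chromatin regulator peaks were higher and 11 lower, against 9 and 13 and 10 and 10 adjusted over all peaks.

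Cell cycle genes lay lower in old ATlo HSCs (deviation -0.79, adjusted p = 0.0042), with 4 of 32 genes having a higher peak and 9 a lower one. The Ccnd2 promoter fell by 0.63 (SE 0.14), that of the topoisomerase gene Top2a by 0.61 (SE 0.17) and that of Mki67 by 0.53 (SE 0.17) in the authors' deposited table. The Cdkn2a promoter, the Cdkn2b peak, the distal Ccne1 peak and the Ccne2 promoter rose by 1.49 (SE 0.28), 1.69 (SE 0.38), 1.83 (SE 0.29) and 0.96 (SE 0.23) in the authors' deposited table. Myeloid genes lay lower (deviation -0.68, adjusted p = 0.0105), with 4 of 29 genes having a higher peak and 5 a lower one, and the promoter of Spi1, which encodes the transcription factor PU.1, fell by 0.63 (SE 0.17) in the authors' deposited table. The Cebpb and Cx3cr1 peaks rose by 0.74 (SE 0.23) and 0.94 (SE 0.32), and the Fcgr3 promoter did not pass (-0.47, SE 0.40) in the authors' deposited table. NF-κB and cytokine genes lay lower (deviation -0.46, adjusted p = 0.0365), with 6 of 31 genes having a higher peak and 7 a lower one. The promoter of Rel, an NF-κB subunit, fell by 0.67 (SE 0.15) while that of its inhibitor Tnfaip3 rose by 1.13 (SE 0.27) in the authors' deposited table. Glycolysis genes lay lower (deviation -0.54, adjusted p = 0.0407), with 5 of 27 genes having a higher peak and 4 a lower one. Random genes gave 6.59 and 2.91. For cell cycle, myeloid and NF-κB genes they gave 7.64 and 3.36, 6.71 and 3.11, and 9.93 and 4.12. Intron 1 of the phosphofructokinase gene Pfkp and the Eno1 promoter rose by 1.47 (SE 0.23) and 1.21 (SE 0.27), and exon 3 of Pfkfb4 fell by 1.90 (SE 0.43) in the authors' deposited table. With the trend in peak level removed, the deviation of mitochondrial regulators shrank to -0.78 (adjusted p = 0.015), that of FoxO genes to -0.50 (adjusted p = 0.0364) and that of chromatin regulators to -0.56 (adjusted p = 0.0301). That of myeloid genes was then -0.81 (adjusted p = 0.0036). Under this setting adjusted p was 0.089 for cell cycle genes (deviation -0.44) and for NF-κB genes (-0.38) and 0.274 for glycolysis genes (-0.30). With promoter peaks alone it was 0.291 for myeloid genes (deviation -0.54), 0.292 for NF-κB genes (-0.44) and 0.318 for glycolysis genes (-0.44). With each gene's smallest-p peak it was 0.0515 for FoxO genes (deviation -1.57), 0.111 for chromatin regulators (-1.10), 0.0897 for myeloid genes (-1.11) and 0.622 for glycolysis genes (-0.44), and the SDs of random lists were more than 0.5.

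The remaining 10 lists did not pass in old ATlo HSCs: adjusted p was 0.316 for autophagy, 0.159 for lysosomal, 0.318 for interferon, 0.0812 for JAK-STAT, 0.185 for AP-1, 0.743 for HSC identity and for lymphoid, 0.207 for megakaryocyte and erythroid, 0.587 for stromal and endothelial, and 0.925 for TGF-β, BMP and Wnt genes. Among autophagy genes 7 of 36 had a higher peak and 4 a lower one, against 8.43 and 3.85 for random genes. A distal peak of Gabarapl2, an LC3 relative, rose by 1.34 (SE 0.23), and the Wdfy3, Optn and Atg14 peaks changed by 0.94 (SE 0.23), 0.75 (SE 0.18) and -2.07 (SE 0.57) in the authors' deposited table. Map1lc3b's promoter did not pass (log2 -0.44, SE 0.17, adjusted p = 0.0713), nor did those of Hlf (-0.45, SE 0.19) and Gapdh (-0.16, SE 0.14) or the distal Hlf peak (1.06, SE 0.51, adjusted p = 0.188), in the authors' deposited table. The Fos and Jun promoters rose by 0.88 (SE 0.18) and 0.71 (SE 0.18) in the authors' deposited table. Intron 1 of Mecom and the Gata2 promoter rose by 1.39 (SE 0.32) and 0.56 (SE 0.17) in the authors' deposited table. Ctsb and Tgfbr1 introns rose by 1.55 (SE 0.18) and 1.85 (SE 0.38), and the Cxcl12 promoter and Plvap exon rose by 0.97 (SE 0.19) and 1.66 (SE 0.25) in the authors' deposited table.

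**Figure D1:**
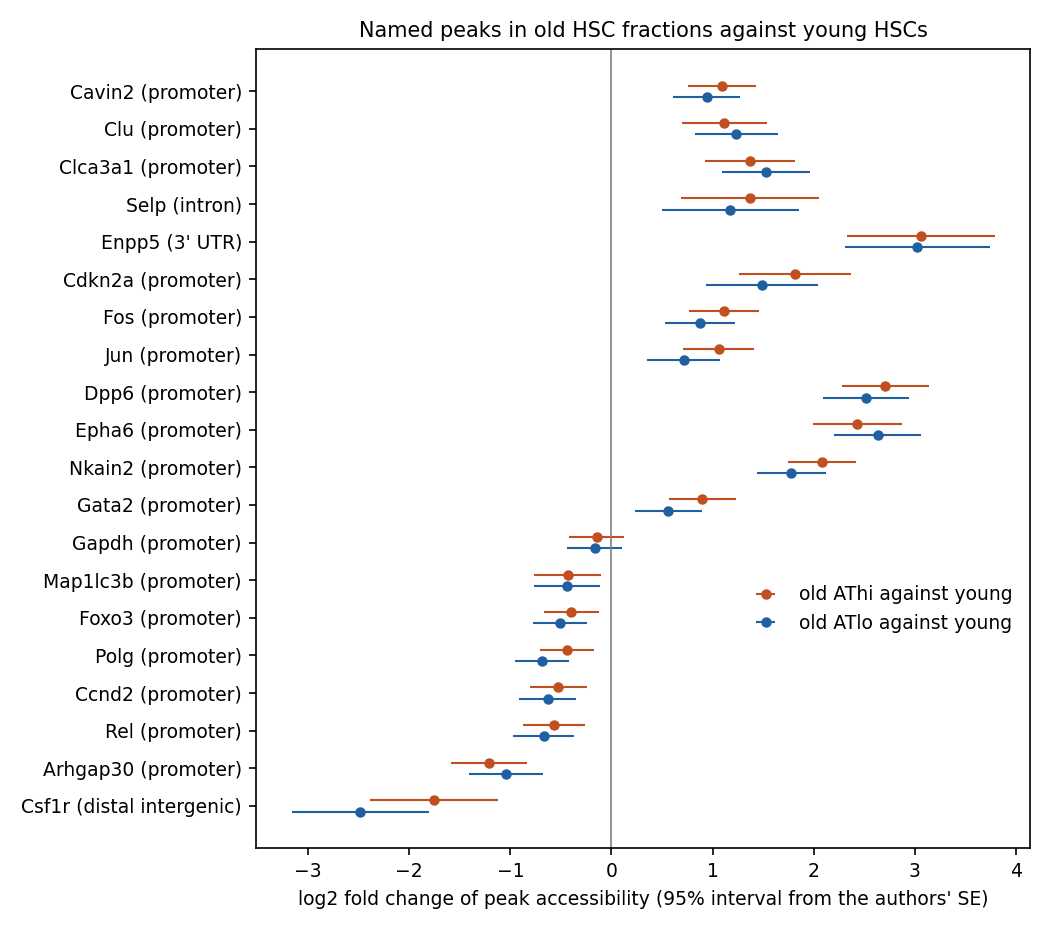
Log2 fold change of accessibility (x axis) of 20 named peaks in old AThi (orange) and old ATlo (blue) HSCs against young HSCs, with 95% intervals from the SEs of the authors' deposited table. The Cdkn2a promoter lies at 1.81 and 1.49, and the distal Csf1r peak at -1.75 and -2.49, in the authors' deposited table.

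Both old fractions shared 4990 higher and 1092 lower calls against young HSCs, and no peak was called in opposite directions. Shared peaks included Cavin2, Clu, Clca3a1, Enpp5, Cdkn2a, Fos, Jun and Dpp6 among the higher ones and Iscu, Emc3, Csf1r, Polg, Ccnd2 and Rel among the lower ones. The shared higher calls were 71.2% of AThi and 78.3% of ATlo higher calls, and the shared lower calls 43.0% and 46.4%. Independent lists of these lengths among the 92579 peaks tested in both would share 482 and 64.5 peaks. Both comparisons use the same 5 young libraries, so unchanged groups were simulated against them 100 times. The simulation gave a mean of 1349 shared peaks among the top higher ranks, where 4987 were observed, and 289 among the lower ranks, where 1090 were observed. The log2 changes of both comparisons correlated at 0.828 across peaks, which are not independent replicates, against 0.340 in the simulation, and 80.2% of peaks had the same sign against 61.5%. Their covariance was 0.319 against 0.0502 simulated, a difference of 0.269. The simulated covariance is the part that the shared young libraries give. The other simulated values show what unchanged groups would give and are not parts of the observed ones. The old libraries are also pairs, O1 to O3, each sorted into both fractions, and what the pairs add to the overlap could not be split off without values per library. Among the 2014 peaks called higher in AThi alone, 99.6% also had a positive ATlo change, and among the 1447 called lower in AThi alone 99.5% had a negative one. The corresponding shares were 99.9% for both the 1380 higher and the 1259 lower peaks called in ATlo alone. A simulated unchanged other fraction gave 92.2% and 84.5% for AThi and 92.1% and 87.5% for ATlo. It took the selected change wholly as noise, which is an extreme case for called peaks. High agreement is therefore possible without a change in the other fraction. How much of it the selection and the shared young libraries gave was not measured.

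Neither old fraction lay nearer to young HSCs under both selections of peaks, but the selections did not mirror each other and leaned toward ATlo. The AThi change was the smaller in size at 52.9% of the 8721 peaks called in ATlo, and at 20.8% of the 9543 peaks called in AThi. Selection on a comparison raises its own changes, so both selections are given. Of the 6082 peaks called in both, AThi was nearer to young at 32.6%, and over all peaks at 46.5%. ATlo was thus the nearer fraction at most peaks of both sets. The changes against young had a larger median SE in AThi (0.334) than in ATlo HSCs (0.321), and noise adds to the size of a change. Among shared higher calls, such as the Enpp5 and Cdkn2a peaks, the median log2 change was 1.34 in AThi and 1.24 in ATlo HSCs, and AThi was nearer at 30.0% of peaks. Among shared lower calls the medians were -0.71 and -0.69, and AThi was nearer at 44.4% of peaks. No separate test of this difference was made.

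No peak differed between old AThi and old ATlo HSCs at an adjusted p under 0.05 in the authors' deposited table, made with DESeq2 per the submitters' processing notes. The smallest unadjusted p belonged to a distal peak of Pou4f3, with a log2 change of -1.31 (SE 0.35, p = 0.00019, adjusted p = 1.00) in AThi relative to ATlo in the authors' deposited table. Other lower peaks with small unadjusted p, none of which passed, lay in the authors' deposited table in the Snora5c 3′ UTR (log2 -1.29, SE 0.35), intron 3 of Klra10 (-1.12, SE 0.31), and distal to Fam133b (-2.80, SE 0.77) and Tnfsf8 (-1.06, SE 0.30). Higher peaks with small unadjusted p, which did not pass either, were distal to Ccdc80 (log2 2.63, SE 0.79, p = 0.000905), Prok2 (1.46, SE 0.44) and Plxna4 (1.73, SE 0.53), and in intron 4 of Traf2 (0.98, SE 0.30) and intron 17 of Vac14 (1.20, SE 0.37, assigned to Mtss2) in the authors' deposited table. The promoters of Map1lc3b (log2 0.01, SE 0.19), Foxo3 (0.11, SE 0.15) and Gapdh (0.02, SE 0.15) differed by less than their SE in the authors' deposited table. An intron 3 peak of Foxo3 changed by -1.72 (SE 0.71, unadjusted p = 0.0154) in the authors' deposited table.

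An unadjusted p under 0.05 was reached by 1683 peaks, 687 higher and 996 lower in AThi, or 1.78% of peaks where chance alone gives 5%. The SD of the Wald statistics was 0.828, and the median 95% half-width of a log2 change was 0.73. The interval lay within a 2-fold change in either direction at 53.6% of peaks, and at the other peaks a 2-fold difference was not excluded. Precision varied with level, and the strongest promoters had a median SE of 0.157. The sources used here do not say whether the fit took account of the old pairs, O1 to O3. The SE of this comparison was 1.11 times that of AThi against young HSCs (median over peaks), near the 1.12 expected of a fit by group alone. A fit with pair terms averaged over the pairs would give the same ratio, so the SEs do not tell these fits apart. A fit that ignores them counts the spread between pairs as noise, which makes p-values too large and can give such a deficit of small ones, so the lack of calls does not show that the fractions are alike.

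**Figure D2:**
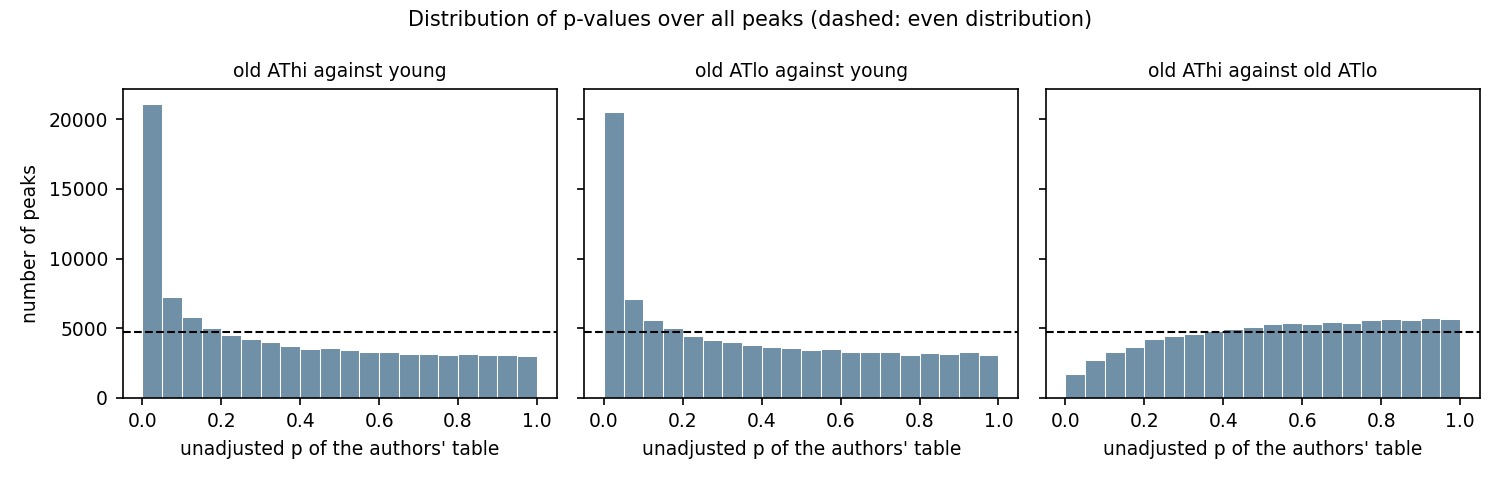
Number of peaks (y axis) by unadjusted p (x axis, in steps of 0.05) in each comparison of the authors' deposited tables, with a dashed line where p-values of unchanged peaks would lie. The lowest step holds 21112 peaks for old AThi against young, 20500 for old ATlo against young and 1683 for old AThi against old ATlo.

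Although no single peak passed, 4 lists lay higher in AThi than in ATlo HSCs against matched random lists: chromatin regulators (deviation 0.34, adjusted p = 0.0045), AP-1 and immediate early genes (0.25, adjusted p = 0.0045), mitochondrial regulators (0.36, adjusted p = 0.0108) and JAK-STAT genes (0.25, adjusted p = 0.0108). No member of them had a called peak, adjusted over all peaks or adjusted over the list alone. The Jun and Fos promoters differed by 0.35 (SE 0.20) and 0.24 (SE 0.19), the Bmi1 promoter by 0.44 (SE 0.20), the Polg promoter by 0.25 (SE 0.16) and the Jak2 promoter by 0.34 (SE 0.18) in the authors' deposited table. When each gene was represented by its peak with the smallest p, none of these 4 lists passed (adjusted p = 0.863 for each). Their deviations were then 0.39, 0.35, 0.34 and 0.34 in the same order, on the wider scale of a gene's most extreme statistic. The SD of random lists rose as well, for chromatin regulators from 0.0868 to 0.257. Relative to the SD, each of the 4 deviations was smaller than with the mean. With the trend in peak level removed, a setting chosen after seeing the data, only chromatin regulators passed (adjusted p = 0.0126), and the deviations were 0.29, 0.10, 0.24 and 0.18. HSC ageing markers gave an adjusted p of 0.674, FoxO genes, HSC identity genes and megakaryocyte and erythroid genes 0.143, NF-κB genes 0.222, interferon genes 0.674, lymphoid genes 0.534 and myeloid genes 0.863. Adjusted p was 0.715 for autophagy, cell cycle and TGF-β, BMP and Wnt genes, 0.775 for lysosomal and glycolysis genes and 0.92 for stromal and endothelial markers.

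**Figure D3:**
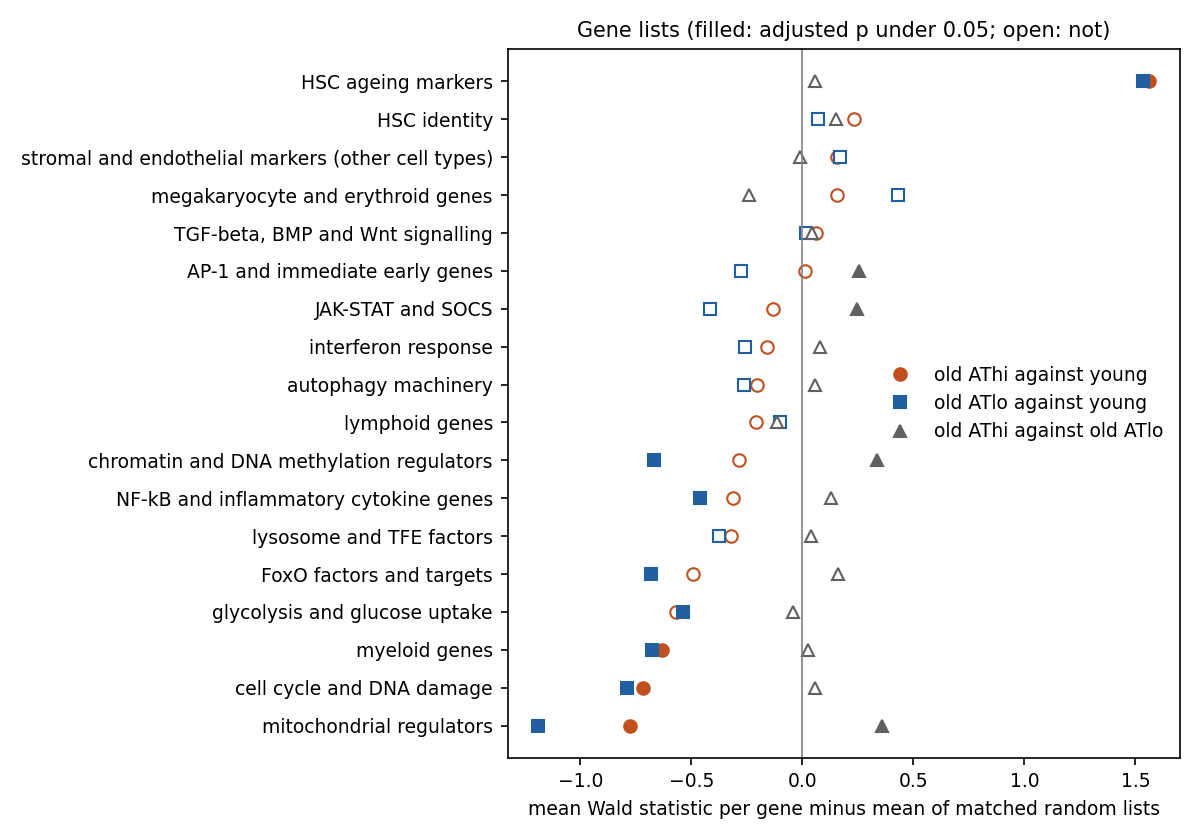
Mean Wald statistic per gene minus that of matched random lists (x axis) for 18 gene lists in 3 comparisons, with filled symbols for adjusted p under 0.05. HSC ageing markers stand at 1.56 (AThi) and 1.54 (ATlo) against young, and mitochondrial regulators at -0.78 and -1.19.

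Promoters such as those of Polg, Ccnd2 and Rel made up a larger share of the peaks that fell than of all peaks. The authors' annotation put 24.2% of peaks in promoters, against 57.9% of the peaks lower in ATlo (odds ratio 4.51, adjusted p = 2.1e-271, Fisher's exact test), 39.9% of those lower in AThi (odds ratio 2.12, adjusted p = 1.57e-68) and 50.4% of those lower in both. Promoters were 20.4% of the peaks higher in ATlo (odds ratio 0.787, adjusted p = 1.06e-13) and 23.1% of those higher in AThi (adjusted p = 0.0634). Exons, such as those of Ubr4 and Plvap, held 5.81% of shared higher calls against 4.22% of all peaks (odds ratio 1.43, adjusted p = 1.64e-07). Peaks are not independent replicates, so these tests describe the called sets. They did not match peaks on level or precision. Promoters of middle level had a median SE of 0.190 in AThi and 0.186 in ATlo against young, where all peaks had 0.334 and 0.321. Smaller falls could therefore be called at promoters, and how much of their share this gives was not measured. The strongest promoters had a median log2 change of -0.22 in AThi and -0.31 in ATlo HSCs.

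Peaks on the X chromosome lay lower by their median in both old fractions, with a log2 change of -0.14 in AThi and -0.09 in ATlo relative to peaks of like level, where autosomes varied with an SD of 0.0146 and 0.0216. Called X-linked peaks went both ways, 104 higher and 103 lower in AThi and 88 higher and 78 lower in ATlo HSCs. A peak at the promoter of Xist, the RNA that silences an X chromosome in female cells, changed by -5.38 (SE 1.56, adjusted p = 0.00927) in AThi and by -4.65 (SE 1.45, adjusted p = 0.0206) in ATlo HSCs in the authors' deposited table. Promoters of Ddx3x and Eif2s3x, which escape that silencing, fell by 0.69 (SE 0.19) and by 1.02 (SE 0.31) in AThi HSCs in the authors' deposited table, and those of Kdm6a (-0.98, SE 0.37) and Kdm5c (-0.84, SE 0.40), which also escape it, did not pass. These X-linked genes were chosen after their values were seen. The labels used here give no sex, and on autosomes alone 6900 peaks were higher and 2436 lower in AThi, and 6282 and 2273 in ATlo HSCs.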

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

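The tests with the trend in peak level removed were chosen after the list results were seen, whereas the list tests themselves were planned. Each list named here differed between the old fractions in the direct comparison of AThi with ATlo HSCs, with no member called, in a test that treats genes as independent. Chromatin and DNA methylation regulators had an adjusted p of 0.0045, AP-1 and immediate early genes 0.0045, mitochondrial regulators 0.0108 and JAK-STAT genes 0.0108, all higher in AThi.

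A candidate explanation is the general trend of the Wald statistic with peak level and promoter status, since strong promoters lay higher in AThi than in ATlo HSCs (median log2 change of 0.09). With it removed, chromatin regulators kept a deviation of 0.29 (SD of random lists 0.0853) of the former 0.34 (SD 0.0868) at an adjusted p of 0.0126, which argues against the trend as their whole cause. For AP-1 genes the deviation shrank from 0.25 (SD 0.0717) to 0.10 (SD 0.0707) at an adjusted p of 0.459, so the trend may account for that call. The deviation of mitochondrial regulators went from 0.36 (SD 0.113) to 0.24 (SD 0.111) and that of JAK-STAT genes from 0.25 (SD 0.0813) to 0.18 (SD 0.0801), both at an adjusted p of 0.126, so trend and list cannot be told apart there because most of the deviation stayed while the call ended. A difference that comes with autophagy engagement stays open for chromatin regulators, untested, and so does correlation between genes, which would make these p-values too small.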

How the results depend on the processing

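Settings that removed the trend with peak level, kept autosomes alone, moved the strongest promoters to a median of 0 or divided Wald statistics by their SD were chosen after seeing the data, and the others were planned. No paired analysis was possible because the tables hold no values per library. For the same reason DESeq2 or other size factors, a count filter, fits of 2 groups, left-out replicates, estimated correlation and splits of the samples gave no value, and the motif alternatives were not run without a genome. The depth behind each library is unknown, so the SEs alone limit what could be called. Between AThi and ATlo HSCs, 0 peaks were called under every threshold, filter and scaling run. The 40 calls named for the smallest p against young HSCs held at an adjusted p under 0.01 and without the authors' filter. Of 126 calls at peaks of list members and other named genes, all held without the filter and 31 did not pass at 0.01, among them Polg (0.0189) and Hlf (0.0456) in AThi and Xist (0.0206) in ATlo HSCs in the authors' deposited table. The scaling that moved the strongest promoters was not applied to single named peaks or to lists. Fewer peaks were called lower under it, so whether the named lower promoters and lower lists hold there is not known.

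For AThi against young, an adjusted p under 0.01 left 864 lower peaks and one under 0.1 gave 4419. The 2-fold limit left 4616 higher and 1025 lower peaks, and promoters alone 1621 and 1012. Moving the strongest promoters to 0 gave 12631 and 802. For ATlo against young the counts were 4090 higher and 661 lower at 0.01, 4149 lower at 0.1, 4154 and 530 with the 2-fold limit, 1297 and 1362 for promoters alone and 16007 and 296 after moving the strongest promoters. Shared calls were 3310 higher and 288 lower at 0.01, and 2116 lower at 0.1. Stricter or looser limits and subsets of peaks change counts by construction, whereas moving the strongest promoters shifts every log2 change and keeps the limit. AThi was nearer to young at 20.8% of peaks called in AThi, 32.6% of those called in both and 46.5% of all. Promoters were 25.5% of higher AThi calls, 22.6% of higher ATlo calls, 35.2% of lower AThi calls and 50.5% of lower ATlo calls at 0.01.

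HSC ageing markers passed in both comparisons with young under each setting. Represented by each gene's peak with the smallest p, 0 lists passed for AThi against ATlo, with an adjusted p of 0.863 for mitochondrial, JAK-STAT, AP-1 and chromatin lists, 1 list passed for AThi against young and 4 for ATlo against young. For AThi against young that setting gave 0.184 for mitochondrial, myeloid and cell cycle lists, and for ATlo against young 0.0515 for FoxO, 0.622 for glycolysis, 0.0897 for myeloid and 0.111 for chromatin lists. With the trend removed, 1 list passed for AThi against ATlo, 2 for AThi against young and 5 for ATlo against young. Adjusted p was then 0.126 for mitochondrial and JAK-STAT and 0.459 for AP-1 lists between the old fractions, 0.194 for mitochondrial and 0.177 for cell cycle lists in AThi, and 0.274 for glycolysis, 0.089 for NF-κB and 0.089 for cell cycle lists in ATlo. Promoter peaks alone gave 0.234 for myeloid genes in AThi, and in ATlo 5 lists passed, with 0.318 for glycolysis, 0.292 for NF-κB and 0.291 for myeloid genes. With the smallest-p peaks the SD of random lists rose for every list, and so did the size of most passing lists' deviations. The scale of the statistic differs between these settings, so the deviations do not compare in size. The cause of the other list changes was not tested. In the other direction, FoxO genes passed between the old fractions with promoter peaks alone (0.0385), and JAK-STAT genes in ATlo against young on autosomes (0.0462).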

Other observations

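The tests of gene families, X-linked peaks and strong promoters were all chosen after the results were seen. Among 221 families of genes that share a name stem, with at least 8 members, only the Mcm family passed. This family includes the subunits of the replicative helicase. It had more promoters lower in both old fractions than random genes matched on promoter level: 4 of 9 against 0.371 (permutation of genes, p = 0.0001, the smallest that the random draws can give, adjusted p = 0.0221). The Mcm2, Mcm4, Mcm5 and Mcm6 promoters fell by 0.53 (SE 0.19), by 0.42 (SE 0.15), by 0.44 (SE 0.15) and by 0.50 (SE 0.15) on the log2 scale in AThi HSCs, and by 0.70 (SE 0.18), by 0.47 (SE 0.15), by 0.51 (SE 0.15) and by 0.42 (SE 0.14) in ATlo HSCs, in the authors' deposited table. In AThi HSCs none of these calls passed at an adjusted p under 0.01 in the authors' deposited table. Mcm7 did not pass in the authors' deposited table (log2 -0.43 and -0.44, adjusted p = 0.0757 and 0.0705). Clec genes had 3 of 18 promoters lower in both fractions against 0.22 for random genes (adjusted p = 0.144). Rpl genes, of ribosomal proteins, had 6 of 41 against 1.5 (adjusted p = 0.199). Collagen genes had 8 of 30 promoters higher in both against 2.71 (adjusted p = 0.494), and none of these families passed.

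X-linked peaks lay lower by their median in both old fractions than in young HSCs, although calls went both ways. Peak level and promoter status did not account for all of it, since after matching on both the X median was still -0.14 in AThi and -0.09 in ATlo HSCs, where autosomes had an SD of 0.0146 and 0.0216. Whether unequal shares of male and female mice among young and old libraries contribute cannot be told, since the labels give no sex. Promoters of Kdm6a, Ddx3x, Kdm5c and Eif2s3x, which escape X inactivation, had a median log2 change of -0.91 in AThi and -0.98 in ATlo HSCs, but they were chosen after their values were seen and so do not decide it. The 21 Y-linked peaks had a matched median of 0.47 in AThi and 0.38 in ATlo HSCs against young, and of -0.02 between the old fractions. Higher Y-linked peaks and a lower Xist promoter are what a larger male share in the old libraries would give. Single Y-linked peaks were imprecise (median SE 0.977 in AThi HSCs against young). The uncertainty of the Y medians was not estimated, so they do not decide it. Weaker X inactivation with age would raise X-linked peaks. A larger male share in the old libraries could hide such a rise, so the lower X medians do not decide it. Changes of X inactivation thus stay open as an untested alternative. The comparisons of autosomal peaks cannot be corrected for sex without values per library.

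The strongest promoters were lower in both old fractions, and 10.8% of them were called lower in AThi and 24.1% in ATlo HSCs. A single scaling factor set too low for the old libraries would move promoters of every level alike, but promoters of middle level lay above the strongest by 0.14 in AThi and by 0.18 in ATlo HSCs, which argues against it as the whole cause. Less signal in strong peaks of every class in the old libraries is a candidate explanation, since 264 other peaks of that level also had a median change of -0.16 and -0.21. Such a loss could come from library quality, from normalisation or from the age of the cells, which cannot be separated with these tables.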
